A study of Mus musculus with 3 samples.

How the data were processed

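RNA with poly(A) tails was sequenced from primary regulatory T cells (Treg cells, the CD4 T cells that restrain other immune cells and depend on the transcription factor Foxp3) of male adult mouse origin, at an age of 4 months. Per the labels, the 3 libraries are technical replicates 1, 2 and 3 of 1 biological replicate, made from RNA sheared by sonication to a size range of 100 to 300. They form 1 group, so no comparison between conditions exists. Every SD over libraries and every p-value for a difference between libraries measures the spread between libraries of 1 biological sample and, as far as the labels go, says nothing of the spread between animals.

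The values are whole-number counts per gene, deposited by the authors as 1 table per library with 22457 versioned Ensembl gene identifiers and no scaling. Per the notes deposited with each table, the counts come from an alignment to mouse assembly mm10 with the GENCODE M4 annotation. The aligner, the counting program, strand use and the handling of duplicate reads and of reads with several matches are not given in the sources used here. Library totals were 3316275 counts in library 1, 3079004 in library 2 and 2782259 in library 3. At these totals, 3 counts correspond to 0.905, 0.974 and 1.08 CPM (counts scaled to a library total of 1e6), which is used as the upper limit that a count of 0 allows. It is a one-sided 95% limit, and the exact two-sided Poisson interval of a count of 0 reaches higher, to 1.11 CPM in library 1 and 1.198 in library 2. Intervals and limits cover counting error only, since sequenced copies of 1 molecule are not independent.

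Gene symbols, coordinates, exon lengths and coding lengths came from the GENCODE M21 annotation of GRCm38, which is the same assembly as mm10 in a later annotation release. Of the 22457 identifiers, 22195 matched a symbol and 262, which held 0.136% of the counts, did not. A coding length was found for 21784. Levels were computed as CPM of the library total, and a gene was called detected at 1 CPM or more in each of the 3 libraries. Levels of different genes are not scaled for length, so orders between genes by CPM also reflect length. Counts per coding base, the mean count over the 3 libraries divided by the coding length, are given where the text turns to count density. This measure was added after the counts of abundant genes were seen to be nearly equal in all libraries. Coding sequences were also searched for 31-mers shared with transcripts of other genes, over 21784 coding genes.

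Each gene's counts were compared between the libraries by a chi-square test of homogeneity against the library totals with 2 degrees of freedom, over the 10043 genes with 30 or more summed counts, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares libraries, not conditions, and allows for Poisson noise only. The index of dispersion used below is the chi-square statistic divided by its degrees of freedom, against the summed counts of the same density class, and equals 1 on average under Poisson noise. The technical coefficient of variation is the square root of edgeR's common dispersion with TMM scaling and filterByExpr. The Poisson intervals of single counts are exact 95% intervals. For each gene list, the median CPM was placed among the medians of 10000 random lists of the same size drawn from genes with any count, without matching on level. The ratio of Cd4 to Cd8a had been planned as the mean of the log2 ratio over libraries. It is given over summed counts with an exact Clopper-Pearson interval, because Cd8a had a count of 0 in 2 libraries.

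Before the data were examined, 36 gene lists with 439 entries and 406 distinct genes were fixed, of which 13 are lists of other cell types. The lists cover Treg identity, pan T cell, resting T cell, effector Treg, T helper lineage transcription factors, effector cytokines, IL-2 receptor and STAT5 signalling, Ikaros, STAT and IRF families, chemokine and S1P receptors, TNF receptor superfamily, inhibitory receptors, DNA methylation and Polycomb, TGF-beta pathway, proliferation, interferon response, immediate early and heat shock, glycolysis, CD8 T cell and cytotoxic, gamma delta T cell, B cell, plasma cell, monocyte and macrophage, neutrophil, dendritic cell, NK cell, erythroid, megakaryocyte and platelet, stromal and endothelial, epithelial, thymocyte, Y-linked and Xist, mitochondrially encoded, replication-dependent histone and housekeeping genes. Of the distinct genes, 402 were measured; Trdc, Xist, mt-Rnr1 and mt-Rnr2 were not analysed here. The share of counts on markers of other cell types leaves out markers that also stand in a T cell list.

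The rule for named genes was also fixed beforehand. It takes Foxp3, Il2ra, Ctla4, Ikzf2, Cd4, Cd8a, Cd3e and Ptprc, the 10 genes with the highest mean level, and any member of the Treg identity, T helper factor, effector cytokine, Ikaros, STAT and Y-linked lists. It takes up to 4 members with the highest and 2 with the lowest mean level of every other list. It also takes up to 10 genes with the largest ratio of the highest to the lowest library among those that passed the test between libraries with a mean of 10 CPM or more. Genes named outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

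Alternatives were TMM and DESeq2 size factors, other detection limits, values per kilobase of exon, other count minimums, edgeR's quasi-likelihood test of each library against the other 2, DESeq2 dispersions, another pseudocount and leaving out each library. Values per kilobase of coding sequence, tests and shares without genes of high count density, and marker sums without the most abundant marker of a list were added after the data were seen. The scripts were tested on simulated data. In 10048 genes with Poisson noise, the chi-square test found 92 of 100 genes changed by 1.5-fold in library 2 and 100 of 100 changed by 2-fold, with 11 unchanged genes called. In 10043 genes with negative binomial noise, the quasi-likelihood test of library 2 found 94 of 100 changed by 2-fold and 100 of 100 changed by 4-fold, with 4 unchanged genes called. In this second simulation, the changed genes had a mean count of 100 or more and every gene had the same dispersion. The result therefore does not give the power in genes with fewer counts or larger dispersions. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 were used.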

Results

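Gene expression was measured by poly(A) RNA sequencing in 3 technical replicate libraries of regulatory T cells from 1 biological sample, with 2782259 to 3316275 counts per library. In all 3 libraries, 10611 of 22457 genes reached 1 CPM. Levels below are the mean ± SD over the 3 libraries, of what the labels call 1 biological sample. Markers of other cells differed between the libraries (below), and whether they came from separate sorts or animals is not settled here, so the SD may not be technical alone. Across the 11296 genes with a mean of 1 CPM or more, the Pearson correlation of log2(CPM + 1) was 0.981 between libraries 1 and 2, 0.979 between 1 and 3 and 0.979 between 2 and 3; genes are not independent replicates.

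Foxp3, the transcription factor that defines the Treg lineage (chromosome X, 7573644 to 7595245, plus strand, GRCm38), was present in every library at 142 ± 6.17 CPM. Its counts were 448, 447 and 407 in libraries 1, 2 and 3. The exact 95% Poisson intervals were 123 to 148, 132 to 159 and 132 to 161 CPM, and they overlapped. The Treg identity list had a median of 316 CPM, above all of the 10000 random lists (percentile 100). Those lists were not matched on level, and housekeeping genes stood at percentile 99.96, so this percentile does not mark Treg cells. Of the 25 Treg identity genes, 23 were detected. The integrin chain Itgae stood highest at 1013 ± 54.1 CPM, followed by Capg at 667 ± 42.9, Nrp1 at 637 ± 48.7, and the TNF receptor family members Tnfrsf18 (GITR) at 588 ± 49.98 and Tnfrsf4 (OX40) at 548 ± 48.6. This order is by CPM without length: per coding base, Itgae had 0.888 counts, below Capg at 1.94, Penk at 2.02 and Tnfrsf4 at 2.05. Il2ra, the alpha chain of the IL-2 receptor (chromosome 2, 11642807 to 11693193), had 316 ± 23.3 CPM, and the inhibitory receptor Ctla4 (chromosome 1, 60887000 to 60915832) had 316 ± 17.1. Ikzf2 (Helios; chromosome 1, 69531214 to 69687245) had 416 ± 29.9 CPM. The ectoenzymes Nt5e and Entpd1, which make adenosine from extracellular nucleotides, had 384 ± 32.7 and 158 ± 21.2. Among secreted products, Ebi3 had 145 ± 9.92 CPM, Il10 19.4 ± 3.12 and Tgfb1 10.4 ± 0.971. The members that missed detection were Plagl1, with 1, 4 and 4 counts, and Il12a, with 0, 2 and 2 counts.

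**Figure D1:**
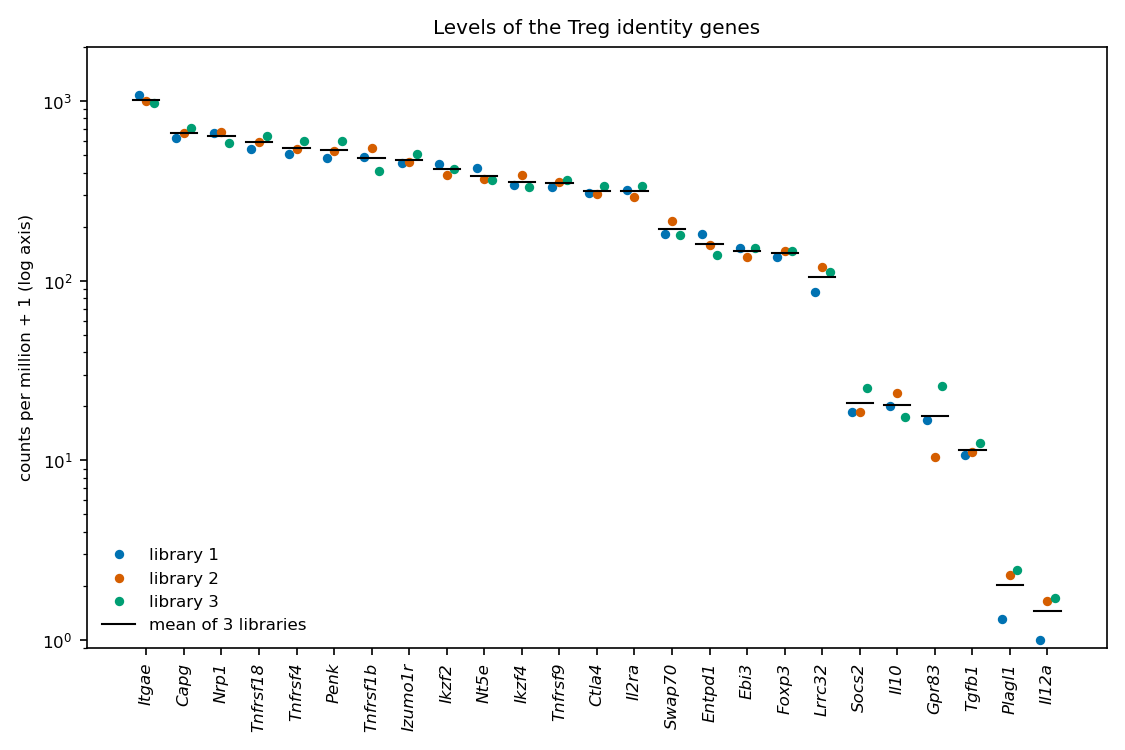
CPM + 1 on a log axis for each gene of the Treg identity list; coloured points are the 3 libraries and black bars their mean. Itgae stands highest at 1013 CPM and Foxp3 at 142 CPM.

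The cells carried a CD4 T cell profile. All 20 pan T cell genes were detected, with a median of 418 CPM (percentile 100). Ptprc (CD45; chromosome 1, 138062861 to 138175708) reached 2151 ± 115 CPM, Lck 981 ± 53.3, Cd6 921 ± 47.0 and Cd2 695 ± 58.0, while Thy1 had 91.0 ± 7.45 and Bcl11b 48.4 ± 11.9. Cd3e (chromosome 9, 44998740 to 45009627) had 403 ± 29.7 CPM. The coreceptor gene Cd4 (chromosome 6, 124864692 to 124888221) had 578 ± 42.5 CPM, and Cd8a (chromosome 6, 71373427 to 71379173) had 0, 0 and 1 counts. The summed counts were 5313 to 1, a ratio of 5313 with an exact interval of 953 to 209891. In libraries 1 and 2, where Cd8a had no count, Cd4 was at least 631-fold and 640-fold higher against a floor of 3 counts. The ratio was 3421 without library 1 and 3393 without library 2, and at least 1271 without library 3, where Cd8a had no count left. Cd8b1, which was chosen after its values were seen, had 24.5 ± 6.51 CPM, so the genes of the CD8 coreceptor were not equally low.

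Effector Treg genes stood above genes of resting T cells. All 25 effector members and all 15 resting members were detected, with medians of 207 CPM (percentile 100) and 68.7 CPM (percentile 97.2). The difference of the medians of log2(CPM + 1), resting minus effector, was -1.68, -1.47 and -1.67 in the 3 libraries (mean -1.61 ± 0.12 SD). Effector examples were the chemokine receptor Cxcr3 at 495 ± 30.5 CPM, Tigit at 480 ± 35.5, Gzmb, which encodes granzyme B, at 466 ± 16.8 and Itgb1 at 409 ± 28.6, with Irf4 at 39.8 ± 8.79 and Areg at 18.3 ± 3.73 lowest. Among resting genes, Il7r had 395 ± 32.9 CPM, S1pr1 306 ± 24.7 and Foxp1 159 ± 15.6, and Bach2 and Ly6c1 had 6.08 ± 2.53 and 4.82 ± 0.821. These are different genes of different lengths, and 3 effector genes lay at or above 1.8 counts per coding base, where counts of most genes varied less than the library totals (below).

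Of the 11 T helper lineage transcription factors, 10 were detected (median 26.2 CPM, percentile 65.2). Gata3, a factor of T helper 2 cells that Treg cells also use, stood highest at 441 ± 54.3 CPM, and Rora had 241 ± 5.04. Tbx21 (T-bet) had 26.2 ± 4.91 CPM and Bcl6 25.04 ± 3.12, and Eomes, with 6, 6 and 2 counts, missed detection. Of 16 effector cytokines, 4 were detected (median 0.174 CPM, percentile 0): Lta at 45.9 ± 11.03 CPM, Tnf at 30.6 ± 6.91, Ifng at 18.8 ± 4.14 and Tnfsf11 at 13.3 ± 6.31. Il17a, Il9, Il6 and Il3 had no count in any library, which allows up to 0.905, 0.974 and 1.08 CPM. Il4 had 2, 0 and 4 counts and Il2 0, 1 and 1.

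The IL-2 receptor and STAT5 signalling list was detected in full (12 of 12, median 99.3 CPM, percentile 99.2). The receptor chains Il2rb and Il2rg had 970 ± 33.9 and 230 ± 17.3 CPM and the kinases Jak1 and Jak3 1055 ± 68.5 and 271 ± 70.1, with Mcl1 at 33.9 ± 4.64 and Socs1 at 28.4 ± 17.4 lowest. All 7 STAT genes were detected (median 289.8 CPM, percentile 100), among them Stat6 at 534 ± 96.8 and Stat4 at 487 ± 11.5, with Stat5a at 102 ± 11.7 and Stat5b at 91.5 ± 21.4. All 5 Ikaros family genes were detected (median 229 CPM, percentile 99.7), and Ikzf2 was followed by Ikzf4 (Eos) at 352 ± 29.3, Ikzf1 at 229 ± 11.4, Ikzf3 at 150.04 ± 7.95 and Ikzf5 at 21.2 ± 4.73, which is uncertain because Ikzf5 shared 98.0% of its coding 31-mers with other genes. All 9 IRF genes were detected (median 175 CPM, percentile 99.9), among them Irf1 at 350.0 ± 10.6.

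Of 19 chemokine and S1P receptors, 16 were detected (median 43.8 CPM, percentile 90.1). After Cxcr3 came Ccr2 at 392 ± 18.2 CPM, Ccr8 at 317 ± 22.2 and S1pr1, while Xcr1 and Cxcr2 had 0.537 ± 0.156 and 0.108 ± 0.188. The TNF receptor list had 11 of 12 members detected (median 188 CPM, percentile 99.98); Tnfrsf1b had 481 ± 72.04, Tnfrsf9 (4-1BB) 351 ± 16.4, Cd40 4.02 ± 1.30 and Ltbr 0.912 ± 0.793. All 10 inhibitory receptors were detected (median 165 CPM, percentile 99.9), among them Cd96 at 438 ± 33.4, Pdcd1 (PD-1) at 312 ± 24.1, Havcr2 at 84.1 ± 7.00 and Cd160 at 36.7 ± 4.44.

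Cell cycle genes were abundant by CPM, which also reflects length. Per coding base, Mki67, with 9531 coding bases, had 0.317 counts and Top2a, with 4584, had 0.742. The proliferation list had a median of 0.427. All 15 proliferation genes were detected (median 143 CPM, percentile 99.9), with the topoisomerase gene Top2a at 1109 ± 58.0 CPM, Mki67 at 988 ± 54.5, Rrm2 at 500.2 ± 29.5 and Ccnb2 at 337 ± 18.6. All 15 interferon response genes were detected (median 113 CPM, percentile 99.8), among them the GTPase genes Ifi47 at 628 ± 19.1 and Igtp at 569 ± 12.7, with Rsad2 lowest at 9.82 ± 2.44. Of 16 immediate early and heat shock genes, 12 were detected (median 27.6 CPM, percentile 70.2), with Nr4a1, which T cell receptor signals induce, at 302 ± 38.4 and Atf3 at 0.220 ± 0.193. The DNA methylation and Polycomb list was detected in full (11 of 11, median 123 CPM, percentile 99.5), with Dnmt1 at 546 ± 67.5 and Dnmt3b at 8.71 ± 1.82. Of 12 TGF-beta pathway genes, 10 were detected (median 14.1 CPM, percentile 38.3), with Smad2 at 124 ± 17.0 and no count on Tgfb2.

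Genes of basic metabolism were uneven. Glycolysis had 14 of 15 members detected (median 134 CPM, percentile 99.9), with Aldoa at 532 ± 27.6 CPM and Pkm at 525 ± 34.8 but Pgam1 at 0.425 ± 0.499. Housekeeping genes were all detected (12 of 12, median 163 CPM, percentile 99.96), with Actb at 637 ± 53.1 and B2m at 282 ± 23.8 but Gapdh at 11.4 ± 2.67 and Pgk1 at 7.86 ± 0.399. Gapdh shared 94.3% of its coding 31-mers with other genes and Pgam1 and Pgk1 100%, so their levels are uncertain. Mitochondrially encoded genes took 0.373% ± 0.034 of the counts, with 7 of 13 detected (median 244 CPM, percentile 100): mt-Nd5 had 927 ± 77.0 CPM and mt-Cytb 728 ± 68.7, and 6 genes, among them mt-Co3 and mt-Nd4l, had no count. Of those 6, all but mt-Atp8 shared 99.05% to 100% of their coding 31-mers with other genes, and mt-Cytb and mt-Nd1 had near-equal counts in all libraries, so this share is not the abundance of mitochondrial transcripts and its spread follows the library totals. Of 13 replication-dependent histone genes, many of which lack a poly(A) tail, 9 were detected (median 5.87 CPM, percentile 19.6), with Hist1h1b at 98.1 ± 11.6. The 4 Y-linked genes analysed were all detected (median 267 CPM, percentile 99.8), with Eif2s3y at 321 ± 22.4, Ddx3y at 301 ± 24.3, Uty at 232 ± 11.9 and Kdm5d at 108 ± 12.4.

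Markers of other cell types together took 0.364%, 0.433% and 0.431% of the counts in libraries 1, 2 and 3. Over the 114 markers under 0.5 counts per coding base, the share was 0.144% ± 0.022. B cell markers, over the whole list, took 0.2004% ± 0.032 of the counts, with 13 of 16 detected (median 16.9 CPM, percentile 46.6). Their highest members were the immunoglobulin gene Ighm at 966 ± 74.9 CPM and Cd74, the invariant chain that associates with MHC class II, at 507 ± 50.1. Ighm had 2966, 2956 and 2904 counts and Cd74 1505, 1584 and 1539. The 13 markers under 0.5 counts per coding base summed to 170, 486 and 428 CPM in libraries 1, 2 and 3 (chi-square test, adjusted p = 1.08e-110). The MHC class II gene H2-Ab1, with 157, 490 and 293 counts, held much of this sum. Without H2-Ab1, the markers summed to 123, 327 and 323 CPM (chi-square test, adjusted p = 2.43e-74). That sum still held the MHC class II gene H2-Aa (144, 404 and 279 counts), which was chosen after its values were seen. All 15 B cell markers tested differed between libraries, also when adjusted over the list alone (15), but the counts of Ighm and Cd74 varied less than the totals they were tested against. The B cell surface gene Ms4a1 (CD20) had 8, 68 and 58 counts. Monocyte and macrophage markers had 6 of 15 detected (median 3.89 CPM, percentile 11.3). Below the same density they summed to 62.1, 145 and 58.2 CPM (chi-square test, adjusted p = 1.63e-35). Itgam, with 131, 181 and 54 counts and 96.0% of its 31-mers shared, held much of this sum, and the other members summed to 22.6, 85.7 and 38.8 CPM, which puts library 3 above library 1 (chi-square test, adjusted p = 5.09e-30). At that density, dendritic cell markers, 4 of 10 detected (median 2.87 CPM, percentile 9.57), summed to 152, 215 and 152 CPM (chi-square test, adjusted p = 2.32e-10). Most of the dendritic cell counts lay on Bst2 (242, 298 and 207 counts) and Irf8 (226, 265 and 166), which also stand in the interferon response and IRF lists. Without Bst2, the dendritic cell markers, Irf8 included, summed to 78.7, 118 and 77.6 CPM (chi-square test, adjusted p = 5.86e-08). Flt3 and Siglech, chosen after their values were seen, had 1, 25 and 6 and 2, 13 and 3 counts, while Zbtb46 had 11, 13 and 15. Plasma cell markers, 3 of 6 detected (median 6.83 CPM, percentile 23.0), summed to 79.6, 88.3 and 105 CPM (chi-square test, adjusted p = 0.00907). Xbp1, with 253, 246 and 205 counts, carried that sum, and the other members summed to 3.32, 8.44 and 31.3 CPM (chi-square test, adjusted p = 5.32e-21). Erythroid markers, 2 of 9 detected (median 1.94 CPM, percentile 9.88), summed to 6.33, 13.97 and 31.6 CPM (chi-square test, adjusted p = 3.42e-13). Without library 1, 5 erythroid and 7 dendritic cell markers were detected.

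**Figure D2:**
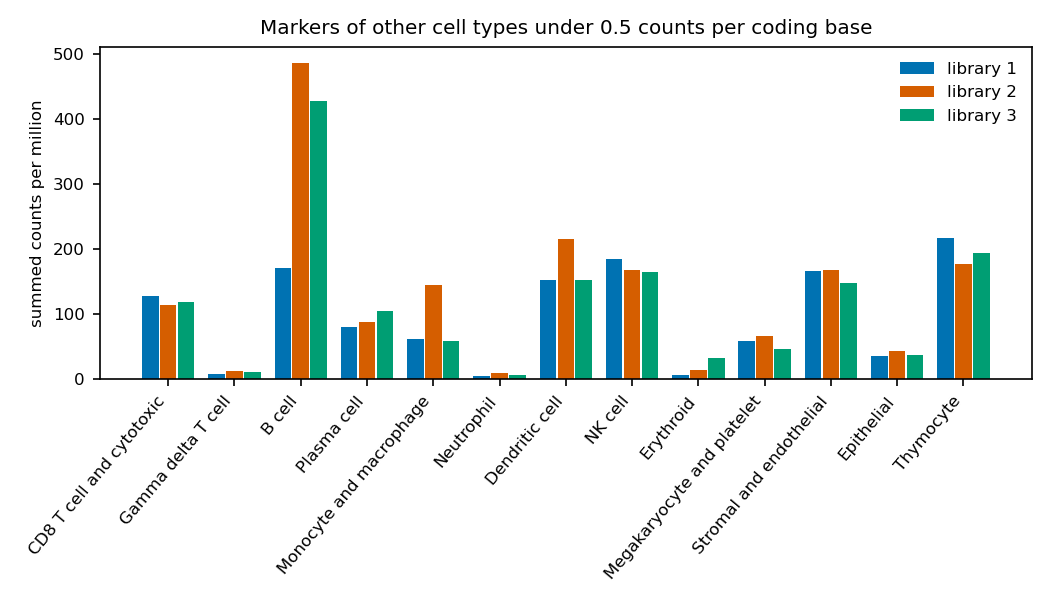
Summed CPM of markers under 0.5 counts per coding base for each list of another cell type, with 1 bar per library. B cell markers stand at 170, 486 and 428 CPM in libraries 1, 2 and 3.

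CD8 T cell and cytotoxic genes had 8 of 9 detected (median 24.5 CPM, percentile 61.4), with Nkg7 at 345 ± 15.3 CPM and Ccl5 at 191 ± 5.89. The remaining lists of other cell types had medians under 1 CPM. NK cell markers had 2 of 10 detected (median 0.773 CPM, percentile 1.87), of which Txk, a T cell kinase as well, had 122 ± 6.89. Gamma delta T cell genes had 3 of 6 (median 0.992 CPM, percentile 5.56), neutrophil genes 1 of 10 (median 0.313 CPM, percentile 0.355), and megakaryocyte and platelet genes 1 of 6 (median 0.228 CPM, percentile 0.585). The megakaryocyte and platelet sum was 58.5, 65.9 and 46.4 CPM (chi-square test, adjusted p = 0.0132) and 1.51, 4.22 and 1.44 CPM without Itgb3 (adjusted p = 0.0649 by the chi-square test). Without library 3, 2 of these markers were detected. Stromal and endothelial genes had 2 of 12 (median 0.211 CPM, percentile 0.030), with Pecam1 at 154 ± 10.02. Epithelial genes had 2 of 6 (median 0.599 CPM, percentile 3.21), with Epcam at 30.7 ± 5.50. Thymocyte genes had 3 of 8 (median 0.439 CPM, percentile 1.23), with Themis at 109 ± 22.3 and no count on Rag1, Rag2 or Ptcra. Their sum was highest in library 1, at 217, 176 and 193 CPM (chi-square test, adjusted p = 0.00335), and 82.6, 85.1 and 91.7 CPM without Themis (chi-square test, adjusted p = 0.559). The sums of the CD8, gamma delta, neutrophil, NK, stromal and epithelial lists did not pass the test, but without their most abundant marker the neutrophil and epithelial sums did. Without Ltf, neutrophil markers summed to only 3, 17 and 7 counts in libraries 1, 2 and 3 (chi-square test, adjusted p = 0.00590). Without Epcam, epithelial markers summed to only 17, 18 and 32 counts (chi-square test, adjusted p = 0.0141).

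Between the technical libraries, 2277 of 10043 genes tested differed beyond Poisson noise (chi-square test, adjusted), and they were kept as separate libraries. Among the 10 genes with the largest ratios at a mean of 10 CPM or more were Jchain (6, 14 and 68 counts), Igha (12, 68 and 128 counts), Ms4a1, Trav5-1, Apoe (11, 84 and 29 counts), Cd79a, Bank1, Ciita and Trbv23 (82, 16 and 35 counts). Jchain was 13.5-fold and Trbv23 4.76-fold higher in the highest than in the lowest library. Of the Treg identity genes tested, 16 of 23 differed, also 16 when adjusted over the list alone. These 16 include Capg, Tnfrsf18, Tnfrsf4 and Penk, whose counts stayed within 5% while the totals they were tested against differed. Of the genes at 1.8 or more counts per coding base, 55 of 80 (68.8%) passed this test, against 1289 of 6655 (19.4%) under 0.2. In between, 27.6% of 2875 genes passed at 0.2 to 1 and 35.4% of 379 at 1 to 1.8. Denser genes also held more counts per gene, which gives the test more power, so this contrast is not one of density alone. The technical coefficient of variation was 9.50% by edgeR's common dispersion and 5.26% as DESeq2's median gene-wise value. The number of differing genes was 1247 without library 1, 1466 without library 2 and 904 without library 3. By edgeR's quasi-likelihood test, which allows for the spread between libraries, 32 genes differed in library 1, 22 in library 2 and 2 in library 3 against the other 2 libraries, 44 in any. In each of these tests, the single library is assumed to vary like the other 2.

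The 10 most abundant genes by CPM included Ptprc, Flna at 1994 ± 320.2, Dock2 at 1754 ± 149.6, Eif4g2, Iqgap1, Ttn at 1448 ± 268, Sf3b1, Eef2 and Arhgap45, and all 10 together took 1.569% to 1.598% of each library. Ttn, with 112076 coding bases, had only 0.039 counts per coding base, whereas Ptprc had 1.69. Counts did not rise far beyond 2 per coding base: of the genes with 300 or more coding bases, 2809 lay at 0.2 to 1, 39 at 1.8 to 2, 19 at 2 to 2.2, 4 at 2.2 to 2.4 and 2 above. Of the 80 genes at 1.8 or more, 61 had a highest library within 5% of the lowest (median 2.49%), whereas the highest library total lay 19.2% above the lowest. Tnfrsf4 had 1671, 1666 and 1670 counts, B2m 864, 858 and 856 and mt-Cytb 2208, 2208 and 2231, while Gzmb (1484, 1454 and 1334 counts), Nkg7 (1086, 1075 and 993) and Ccl5 (612, 590 and 546) varied more. The median log2 ratio of library 1 to library 3 was 0.27 in the 6655 genes under 0.2 counts per coding base. It fell to 0.21 in the 2875 genes at 0.2 to 1, 0.10 in the 379 at 1 to 1.8 and 0.03 in the 80 at 1.8 or more. Relative levels among genes near 2 counts per coding base, and their CPM differences between libraries, are therefore uncertain as differences in abundance. These include Capg, Tnfrsf18, Tnfrsf4, Penk, Cd2, Lck, Tigit and Ighm. The shift was graded, so genes at 1 to 1.8 are uncertain to a lesser degree, such as Ptprc, Ctla4 at 1.44, Cd4 at 1.29 and Il2ra at 1.11. Foxp3, at 0.34, lies below 1.

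**Figure D3:**
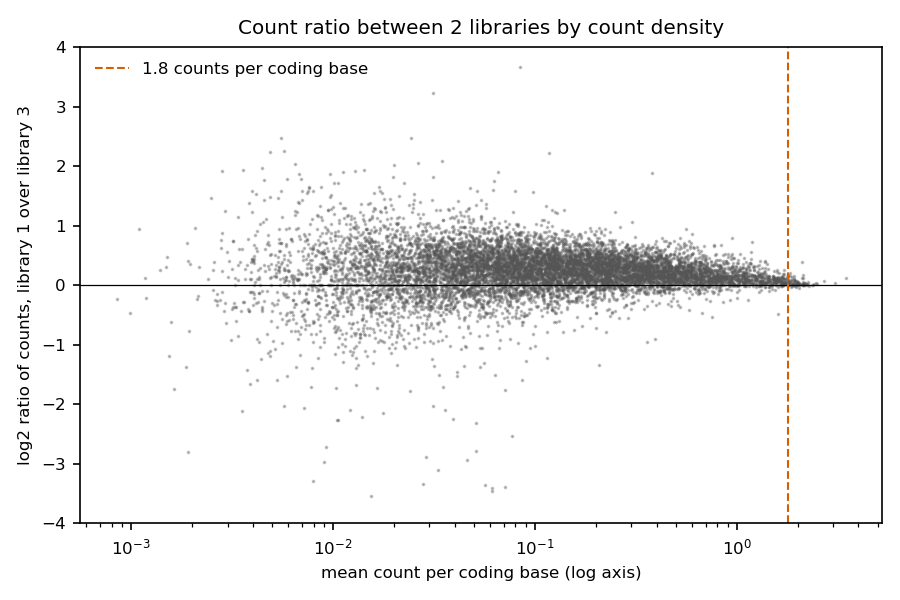
Each point is a gene with 30 or more summed counts; the x axis is its mean count per coding base (log axis) and the y axis the log2 ratio of its counts in library 1 over library 3. The median ratio was 0.27 under 0.2 counts per coding base and 0.03 at 1.8 or more (right of the dashed line).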

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

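The tests and shares restricted by count density, the marker sums without the most abundant marker and the values per kilobase of coding sequence were chosen after the data were seen; the other alternatives were fixed before the data were examined. Of the alternative values of the main results, 61 stayed within the limit set for each (1.5 times for a count, 1 SD or the counting interval for a level) and 12 moved. A change of sign was possible only for the resting minus effector difference, since the other main results cannot be negative. That difference stayed negative under each alternative run. Genes detected, list members detected, Treg identity members detected, the Cd4 to Cd8a ratio and the mitochondrial share stayed within their limits under each alternative. Of the values per gene list, 260 stayed and 33 moved. Genes differing between libraries numbered 904 to 1466 with 1 library left out, where fewer libraries enter the test, 1184 among the 6655 genes under 0.2 counts per coding base (1289 of them in the main test), where fewer genes are tested, scaled by their own totals and adjusted among themselves, and 44 by the quasi-likelihood test, which counts the spread between libraries as noise. The technical coefficient of variation was 8.18% to 10.2% with 1 library left out, 5.26% as DESeq2's median gene-wise value and 11.8% in genes under 0.2 counts per coding base; the cause of these shifts was not tested. Foxp3 was 113 on the scale per kilobase of exon, which is another unit. The share of other cell type markers was 0.144% over markers under 0.5 counts per coding base, which are fewer genes. The resting minus effector difference was -1.87 per kilobase of exon and -2.22 per kilobase of coding sequence, the same direction; the cause was not tested. No paired analysis was possible because the labels give 1 group. Depth limits genes under 3 counts per library. Genes near 2 counts per coding base are limited by nearly equal counts in all libraries, the cause of which stays open.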

Other observations

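T cell receptor variable genes, a family chosen after the data were seen, were broadly represented. Of 21 beta chain variable genes (Trbv), 20 were detected, led by Trbv3 at 178 ± 21.2 CPM, Trbv13-2 at 136 ± 5.64 and Trbv5 at 129 ± 5.72. Of 99 alpha chain variable genes (Trav), 53 were detected, led by Trav3-3 at 29.1 ± 1.06 and Trav12-2 at 26.7 ± 3.72. This order is uncertain where genes share sequence: Trav3-3 shared 70.6%, Trav12-2 51.9% and Trbv5 85.5% of their 31-mers with other genes. Immunoglobulin kappa variable genes (Igkv) had none of 102 members detected in every library, but their sum was 21, 170 and 377 counts in libraries 1, 2 and 3 (chi-square test, p = 5.11e-90), and heavy chain variable genes (Ighv) summed to 33, 65 and 107 (chi-square test, p = 9.55e-13). Igkv12-44 had 0, 3 and 42 counts and Igkv4-91 0, 36 and 9.

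All tests in the paragraphs that follow were chosen after the results were seen, and so were the genes Trac, Rpl13a, Tpt1, Ywhaz and Slc16a3 named there. The libraries share 1 group and 1 biological sample, so the design names no biological difference between them to test.

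Most genes of high count density had nearly equal counts in all libraries: the 80 genes at 1.8 or more counts per coding base had a mean index of dispersion of 0.470 (95% bootstrap interval 0.318 to 0.669), where Poisson noise gives 1. That a high count alone gives this was argued against, since 1033 genes with as many counts but under 0.5 counts per coding base had an index of 6.22 (5.85 to 6.66). One library deposited 3 times was argued against by an index of 2.93 (2.83 to 3.04) in genes under 0.2 counts per coding base. A candidate explanation is removal of reads that start at the same position before counting. Keeping 1 read per position and strand would allow at most 2 counts per coding base, if only reads within the coding sequence were counted. However, 25 genes with 300 or more coding bases lay above 2, with Trac at 2.70 and B2m at 2.41. Removal of such reads stays open, because coding lengths come from a later annotation release. The handling of duplicate reads and of reads outside the coding sequence is not given in the sources used here.

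B cell markers were lower in library 1. Counting noise of independent reads was argued against by the chi-square test of the summed markers (p = 8.32e-112), and depth by the marker rate of libraries 2 and 3, which was 2.70-fold (exact interval 2.46 to 2.96) that of library 1, the deepest. RNA from B cells in libraries 2 and 3 may contribute: 221 immunoglobulin variable genes outside the marker list, whose values had also been seen, were 4.74-fold higher per count in library 2 (exact interval 3.55 to 6.41) and 10.6-fold in library 3 (8.10 to 14.2) than in library 1. Plasma cells express these genes too, and the most abundant B cell genes cannot test it, since Ighm (2966, 2956 and 2904 counts) and Cd74 lie at a density where counts vary little. The pattern was not particular to B cells. Without the most abundant marker of each list, plasma cell, monocyte and macrophage, neutrophil, erythroid and epithelial sums were also lowest in library 1 and passed the chi-square test. The CD8 and NK cell sums were highest in library 1 but did not pass it. Whether the libraries came from separate cell sorts stays open.

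Some genes that most cells use had few counts. Among the glycolysis, housekeeping and mitochondrially encoded genes, 14 lay under 0.2 counts per coding base. They shared a median of 99.5% of their coding 31-mers with other genes, against 24.2% in the other 24 (one-sided permutation p = 0.0182). The permutation takes genes as independent. The 14 include 6 mitochondrially encoded genes that may not be, so the p-value can overstate the evidence. Leaving reads that match several genes out of the counts could give such a difference. Rpl13a and Tpt1 had 97.6% and 100% shared but 243 ± 19.2 and 60.6 ± 13.4 CPM. They decide neither way, because only coding 31-mers were searched. Reads that are longer or lie outside the coding sequence can still match 1 gene alone. The low gene mt-Atp8 had 5.85% shared and no count. Only transcripts, not the rest of the genome, were searched for shared 31-mers, so mt-Atp8 decides neither way. A low transcript level could not be excluded: of the 6 low genes with 20 or more unmatched positions, 1 (Ywhaz) reached 1.8 counts per such position, while Hk2 and Slc16a3 shared no 31-mer and were low.

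Across 4260 genes of low density, the log2 ratio of counts correlated with coding GC content at -0.27 for libraries 1 and 2, -0.07 for 1 and 3 and 0.18 for 2 and 3 (Pearson, across genes, which are not independent replicates).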
